A study of Mus musculus with 4 samples.

How the data were processed

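RNA-seq libraries of C2C12 mouse myoblasts transfected with wild-type lamin A (2 samples) or K97E lamin A (2 samples) were analysed from the per-library transcript files deposited by the authors. Per the labels' protocols, 3 µg of DNA was transfected with a lipid reagent, cells were harvested after 24 h, and libraries were made with a stranded kit and sequenced as paired reads of 100 bases. Samples were grouped by the genotype label. The submitters' processing notes name HISAT2, SAMtools, FastQC, DESeq2 and StringTie 2.1.7 with the build GRCm39. Per the file headers, StringTie 2.1.7 was run in its mode that estimates annotated transcripts only, with the Ensembl release 104 annotation and no strand option. What role DESeq2 had is not given in the sources used here, and DESeq2 was not used here.

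Per the file headers and the values, each deposited file gives coverage, FPKM and TPM for the same 142434 transcripts, and coverage for each exon. The authors' TPM values sum to 1000000 in each library, and deposited coverage divided by FPKM was constant within a library (10.8, 12.76, 13.85 and 12.99), which gives the aligned gigabases behind the FPKM values. The files hold no read counts. Estimated reads, coverage times transcript length divided by the read length of 100, came to between 89600000 and 115600000 per library. These estimates are not whole counts, so no counting interval was computed. StringTie divides reads among overlapping transcripts by a model, and with no strand option reads of a gene and of an antisense neighbour can be credited to either. Of the tested genes 3538 have exons that overlap exons of another measured gene.

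Gene values were the sum of TPM over a gene's transcripts, for 55416 genes. They were divided by median-of-ratios factors over genes with TPM above 1 in all libraries (0.98, 0.98, 1.04 and 1.00), and a pseudocount of 0.5 was added before log2. Genes with a mean TPM of at least 0.5 were kept (16304). Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend, 5.54 total degrees of freedom), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. With 2 samples a group, an exact permutation test could not go below 0.333. Fold changes are K97E minus wild type on the log2(TPM + 0.5) scale. TPM means and SDs are of the deposited values before scaling.

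Gene lists (26) were fixed before the data were examined, as were the tests and most of the other settings tried. Lists with at least 5 measured members (21) were tested with limma's camera with an inter-gene correlation of 0.01, with the correlation estimated, and with fry. Of 919 list entries, 11 symbols did not occur in the files. The genes named were Lmna, then the 12 largest changes in each direction among called genes at a mean TPM of at least 1 with groups that do not overlap and a symbol that is not a predicted-gene name. With fewer than 5 such genes in a direction, which held for both, the 10 with the smallest unadjusted p were taken under the same other conditions. Interleukin and chemokine ligands at an unadjusted p under 0.05, called receptors up to 6, and of each other list up to 4 called members or the 2 with the smallest p were added. A gene selected by this rule is not reported here.

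The test was checked on simulated data. Values for 16064 genes were drawn with variances from limma's prior, and 53 of 100 genes changed 2-fold and 88 of 100 changed 4-fold were called, with 10 false calls. A simulated list of 20 genes shifted by 0.4 was found and 0 of 21 other lists were called. Genes were independent in the simulation, so it does not test correlation within lists. The simulated noise met limma's own assumptions, so the rates for genes may not hold for the real libraries. Biotype, GC content and transcript length came from GENCODE annotation of another build, matched by gene ID alone for 98.5% of tested genes. Its coordinates were not used, and positions are those of the files in GRCm39. Alternatives were other pseudocounts, filters and scalings, FPKM as deposited, eBayes without trend or with robust settings, voom weights on the estimated reads, protein-coding genes only, the replicate number as a block, and each library left out. Files were read with Python 3.11.15 and pandas 2.3.3, and figures drawn with matplotlib 3.10.9.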

Results

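RNA was sequenced from C2C12 cells, a mouse myoblast line that can be grown as dividing precursors or differentiated into muscle fibres. The cells had been transfected with DNA for wild-type lamin A or for K97E lamin A, which the labels describe as a mutant of dilated cardiomyopathy, and were harvested 24 h later. Lamin A is a filament protein of the nuclear lamina, encoded by Lmna. There were 2 libraries in each group, described in the labels as biological replicates, and no untransfected cells were analysed here. The labels do not say whether replicates came from separate cultures or transfections, so p-values measure the spread between these samples, which may be technical. The coverage in the files corresponded to about 89600000 and 106400000 reads of 100 bases on transcripts in the wild-type libraries, and 115600000 and 107800000 in the K97E libraries. Between 14463 and 14684 genes reached 1 TPM (transcripts per 1000000) in each library, and 16304 genes with a mean TPM of at least 0.5 were tested. Over tested genes the log2 values of the wild-type libraries had a Pearson correlation of 0.9849. Each pair of a wild-type and a K97E library lay above that, at 0.9866 to 0.9895, and the K97E libraries stood at 0.9911. The wild-type libraries were thus no more alike than libraries of different groups.

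Lmna was abundant in all 4 libraries. Lmna (ENSMUSG00000028063; GRCm39 chromosome 3, 88387454 to 88417263, minus strand) stood at 577 ± 27 TPM (SD, n = 2) with wild-type lamin A and 645 ± 21 TPM (SD, n = 2) with K97E. The log2 fold change was 0.10 (SE 0.10), and limma gave an adjusted p of 0.965; the fold change was 0.05 without wild-type replicate 1, 0.16 with TPM as deposited and 0.18 with quantile normalization. The 12-exon transcript ENSMUST00000029699 stood at 250 and 303 TPM in the wild-type libraries and 339 and 300 TPM in the K97E libraries. The 10-exon transcript ENSMUST00000120377 stood at 293 and 278 TPM, and at 303 and 314 TPM. Which species the transfected DNA came from is not given in the sources used here, and reads from it cannot be separated from reads of the cells' own gene in these values. Lmna therefore does not check the labels of the groups.

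The first comparison asked which genes differed between cells given K97E and cells given wild-type lamin A. Mfsd4a, a transporter-like membrane protein of the major facilitator superfamily, rose from 0.687 ± 0.025 TPM (SD, n = 2) to 11.4 ± 0.21 TPM (SD, n = 2). Its log2 fold change was 3.28 (SE 0.14, limma adjusted p = 0.0157), on the scale of log2(TPM + 0.5), which understates the change of weakly expressed genes. It was the only gene called among 16304, and no gene was called lower. At an unadjusted p under 0.05 there were 600 genes, 186 higher and 414 lower, where chance alone would give about 815. Mfsd4a (ENSMUSG00000059149) lies on GRCm39 chromosome 1, 131950544 to 131995800, minus strand, and overlaps Elk4 on the plus strand. In the K97E libraries at least 98.3% of the bases credited to Mfsd4a lay in 1 exon of ENSMUST00000144548, at 131954546 to 131956285, inside the Elk4 gene span of 131935345 to 131960350. No coverage was credited to that exon in the wild-type libraries, whereas a 95 bp exon of another Mfsd4a transcript inside it had a coverage of 49.9 and 60.1. The nearest annotated Elk4 exons end at 131954186 and start at 131959302, so none overlaps the exon of ENSMUST00000144548. No strand option stands in the recorded command, so whether these reads came from the Mfsd4a or the Elk4 strand is uncertain. The call was lost with the replicate number as a block (adjusted p = 0.108) and without either K97E library (adjusted p = 0.0862 without replicate 1 and 0.169 without replicate 2). It was also lost with no filter on low genes (adjusted p = 0.912). TPM without further scaling gave 1 gene higher and 1 lower, the predicted gene Gm28116, which was named after its values were seen.

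**Figure D1:**
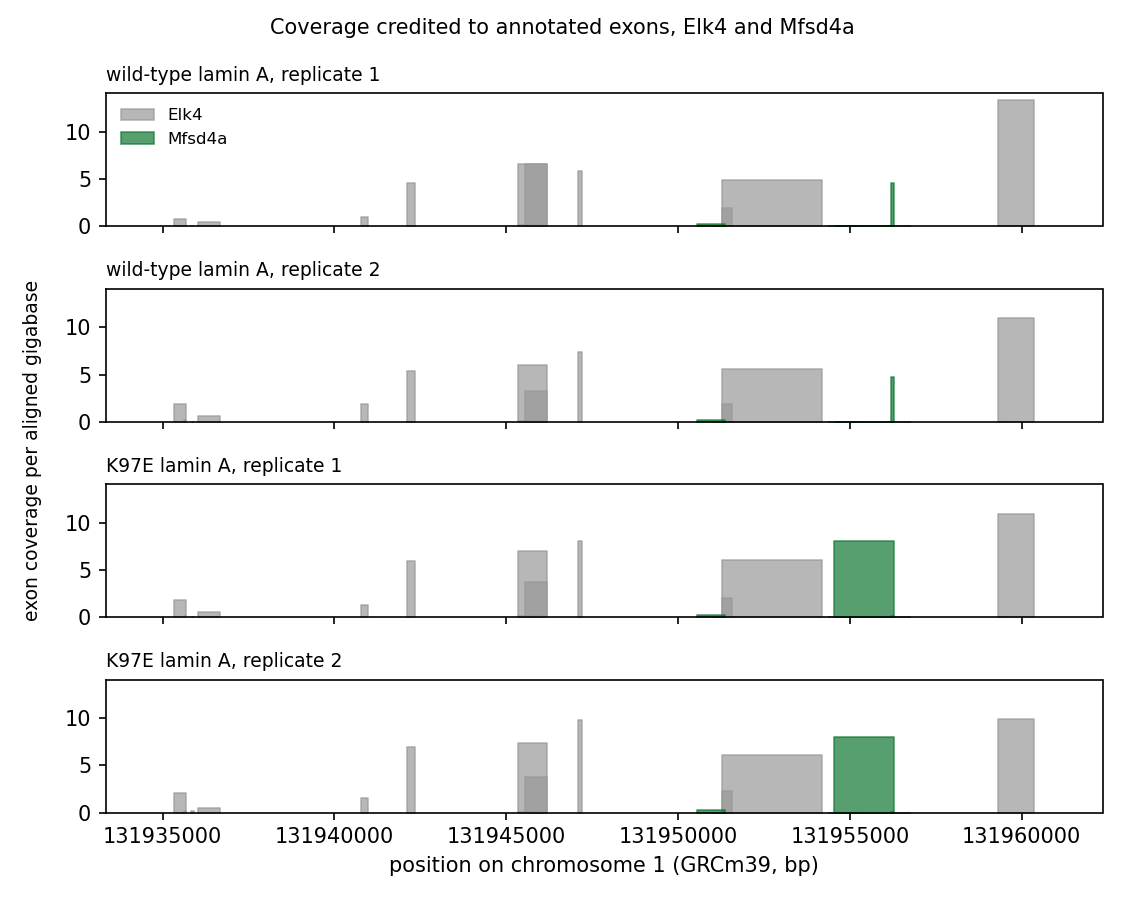
Coverage credited to each annotated exon of Elk4 (grey) and Mfsd4a (green), per aligned gigabase (vertical axis), against position on chromosome 1 of GRCm39 in bp (horizontal axis), with 1 panel for each of the 4 libraries. The wide Mfsd4a exon at 131954546 to 131956285 carries coverage in the K97E libraries alone, 8.12 and 7.97 per gigabase, while the wild-type libraries carry 4.62 and 4.71 in the 95 bp exon inside it.

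Beyond Mfsd4a fewer than 5 genes were called in either direction, so the 10 genes with the smallest unadjusted p in each direction, in groups that did not overlap, are described by their values. Nos2, the inducible nitric oxide synthase, stood at 29.7 ± 11.7 TPM (SD, n = 2) with wild-type lamin A and 4.69 ± 0.80 TPM (SD, n = 2) with K97E, a log2 difference of -2.55 (SE 0.29, limma adjusted p = 0.336). Lcn2, the iron-carrier-binding protein lipocalin 2, stood at 39.9 and 55.4 TPM and at 12.3 and 17.2 TPM. The chemokine Cxcl1 differed by -1.08 and the growth factor Fgf7 by -0.58 on the log2 scale. The same set held Frg2f1, Eif1ad14, Ifi209, Ifitm6, Sh2d6 and the TNF receptor family member Tnfrsf9, with log2 differences from -1.49 to -0.55. On the higher side Pdxp, which overlaps another measured gene, differed by 0.92, Mirt1 by 1.06, and Lss, the lanosterol synthase of cholesterol synthesis, by 0.48. Mir6972, Mir6988, Lfng, Zfp968, B4galt2 and Mrc2 made up the rest, with log2 differences between 0.37 and 0.86. The upper end is Mir6988, which rested on as few as 2 estimated reads in a library, and Mir6972 on as few as 12. With voom weights Frg2f1 stood at -0.88 and Zfp968 at 1.06, and with FPKM as deposited Mirt1 stood at 0.70. Eif1ad14 belongs to a family of similar copies, among which reads can be shared, and B4galt2 also overlaps another measured gene. None of these genes except Mfsd4a passed over all genes tested in the main fit. Groups did not overlap for 33.1% of tested genes, where chance gives 33.3%.

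The series title names interleukin and chemokine signalling, and the second comparison asked how those genes stood. Chemokine genes were lower as a group with K97E: 15 of the 19 measured had a negative fold change, and the mean log2 fold change was -0.45. Ccl2, a monocyte attractant, stood at 2007 ± 15 TPM (SD, n = 2) with wild-type lamin A and 1489 ± 149 TPM (SD, n = 2) with K97E. Cxcl1, a neutrophil attractant, stood at 702 ± 39 TPM and 348 ± 64 TPM (SD, n = 2 each). Interleukin genes were also lower as a group, with 8 of 9 measured members negative and a mean of -0.28. Among them Il6 stood at 29.4 ± 9.2 TPM and 14.7 ± 1.5 TPM (SD, n = 2 each). In the limma camera test against other genes, with a preset correlation of 0.01, adjusted p was 9.81e-07 for chemokines and 0.00168 for interleukins. With an estimated correlation the camera adjusted p was 0.358 for each, so neither call held. The estimate was 0.0125 for chemokines, near the preset value, and -0.105 for interleukins. A higher correlation within these lists therefore does not account for the loss. With an estimated correlation, camera takes its degrees of freedom from the few libraries, and with a preset one from the number of genes. For chemokines the unadjusted camera p was 1.87e-07 with the preset and 0.0361 with the estimated correlation. The loss therefore does not decide whether these lists differ. The interleukin call was also lost with no filter (adjusted p = 0.0592, mean -0.16). No member of either list passed over all genes tested in the main fit. Adjusted over the list alone, the chemokines Cxcl1, Ccl11 and Cxcl5 fell, with limma adjusted p of 0.0168, 0.0397 and 0.0397, and the interleukin Il6 fell, with 0.0469. Adjusted over ligands and receptors together, Cxcl1 passed with 0.0496, and Ccl11, Il6 and Cxcl5 stood at 0.0703. Because the title may have been chosen on these samples, the lists are not independent evidence of a direction.

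The remaining ligands at an unadjusted p under 0.05 were all lower by value with K97E. Il33 differed by -0.51, Il1rn by -0.38, Ccl8 by -0.47, Ccl7 by -0.46 and Cxcl9 by -1.59 on the log2 scale. Without K97E replicate 1 these were -0.33 for Il33, -0.27 for Ccl8 and -1.04 for Cxcl9. Cxcl9 stood at 36.6 and 11.8 TPM in the wild-type libraries, and its log2 difference was -0.80 without wild-type replicate 1 and -2.39 without wild-type replicate 2. The eotaxin gene Ccl11 differed by -1.24 (SE 0.27) and Cxcl5 by -1.06 (SE 0.25). The 28 measured receptors had a mean log2 fold change of -0.09, with a camera adjusted p of 0.426 and no called member, over all genes or adjusted over the list alone. Without K97E replicate 2 the receptor list passed, with 0.00711 and a mean of -0.20, and without K97E replicate 1 its mean turned to 0.0078. Without wild-type replicate 1 the mean was -0.05 and without wild-type replicate 2 it was -0.14.

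**Figure D2:**
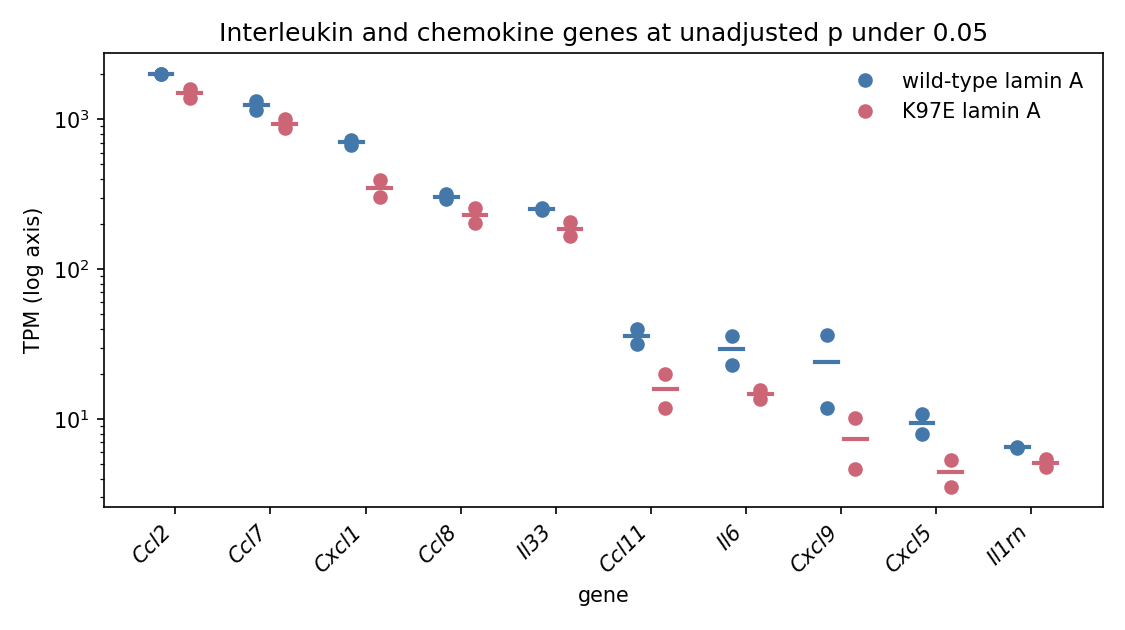
TPM on a log axis (vertical) for each interleukin and chemokine gene at an unadjusted p under 0.05 (horizontal), with a point for each library and a bar at the mean of the 2 libraries of a group. Each gene has both K97E libraries below both wild-type libraries, from Ccl2 at 1384 and 1595 TPM against 1996 and 2017 TPM to Il1rn at 5.38 and 4.78 TPM against 6.54 and 6.39 TPM. The genes were picked by a test on these same libraries, which favours such separation, so it is not further support.

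Genes of inflammatory and interferon responses were lower as groups with K97E as well. Of 80 measured interferon-stimulated genes 73 had a negative fold change, with a mean of -0.20, and of 33 genes of the NF-kB and TNF response 29 did, with a mean of -0.31. Of 17 genes that sense nucleic acids in the cytosol 14 were negative, with a mean of -0.23. The camera adjusted p values were 1.48e-12, 2.26e-10 and 0.000268. With an estimated correlation, of 0.446, 0.174 and -0.018, the camera adjusted p values were 0.506, 0.406 and 0.358. In the main fit no member of these lists passed over all genes, and adjusted over the list alone only Lcn2 of the NF-kB and TNF list fell. The guanylate-binding protein Gbp5 differed by -0.70, Ifit1bl1 by -1.09, the NF-kB regulator Nfkbiz by -0.47, the inflammatory caspase Casp4 by -0.36 and the RNA sensor Tlr3 by -0.39. For the interferon list wild-type replicate 2 and K97E replicate 2 lay close together, with mean deviations of 0.008 and -0.013 against 0.19 and -0.19 for the other libraries. Its mean log2 fold change was -0.11 without wild-type replicate 1 and -0.11 without K97E replicate 1. The 30 measured JAK-STAT components had a camera adjusted p of 0.188, with Pim1 at -0.33 and Osmr at -0.21.

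Genes of cholesterol synthesis and uptake were higher as a group with K97E. All 25 measured members had a positive fold change, with a mean of 0.24 on the log2 scale, and 11 had an unadjusted p under 0.05. Lss stood at 9.75 ± 0.51 TPM with wild-type lamin A and 14.4 ± 0.43 TPM with K97E (SD, n = 2 each). The camera adjusted p was 1.22e-13, and with an estimated correlation, of 0.167, the adjusted p was 0.358. No member passed over all genes or adjusted over the list alone.

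**Figure D3:**
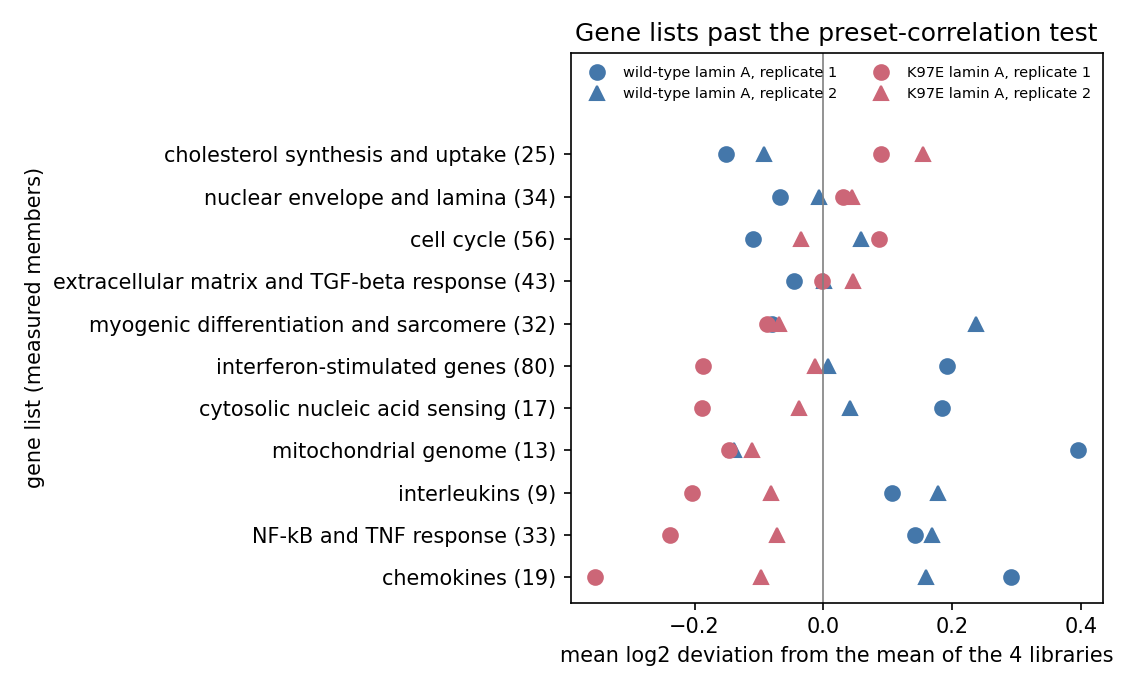
Mean log2 deviation of each library from the mean of the 4 libraries (horizontal axis) for the 11 gene lists past the camera test with a preset correlation (vertical axis), with blue for wild-type and red for K97E lamin A, circles for replicate 1 and triangles for replicate 2. For chemokines the K97E libraries sit at -0.35 and -0.10 and the wild-type libraries at 0.29 and 0.16, and for cholesterol genes the K97E libraries sit at 0.09 and 0.15 and the wild-type libraries at -0.15 and -0.09.

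The other lists past the camera test moved less or rested on particular libraries. Nuclear envelope and lamina genes were higher as a group (34 measured, mean 0.07, adjusted p = 0.0257), with the lamin B receptor Lbr at 0.25 and Plpp7 at 0.54. Their adjusted p was 0.496 with an estimated correlation, and the list passed under 13 of 20 alternatives. The call was lost without either wild-type library or K97E replicate 2 (adjusted p = 0.134, 0.0603 and 0.164), with a mean TPM of at least 5 (0.075) and with protein-coding genes only (0.0561). The mean was 0.04 without wild-type replicate 1 and 0.13 with TPM as deposited, and Plpp7 stood at 0.19 without wild-type replicate 1 and 0.88 without wild-type replicate 2. Myogenic and sarcomere genes were lower as a group (32 measured, mean -0.16, adjusted p = 0.00345), with the acetylcholine receptor subunit Chrna1 at -0.37 and desmin, Des, at -0.20. Their adjusted p was 0.496 with an estimated correlation, 0.614 without wild-type replicate 2 and 0.0511 without K97E replicate 1. Without wild-type replicate 1 and replicate 2 in turn, the mean of the list was -0.32 and -0.0043, and Des stood at -0.31 and -0.10. Mitochondrial genome transcripts were lower (13 measured, mean -0.26, camera adjusted p = 0.00311), with an adjusted p of 0.815 with an estimated correlation, of 0.99. They made up 7.37% of TPM in wild-type replicate 1 and between 5.29% and 5.55% in the other 3 libraries. Their mean turned to 0.0075 without wild-type replicate 1 and was -0.52 without wild-type replicate 2. The call was lost without K97E replicate 1 (0.0511), with no filter (0.083) and with quantile normalization (0.0701), under which the mean was -0.10.

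Cell cycle genes (56 measured, mean 0.05, adjusted p = 0.0373) and extracellular matrix and TGF-beta response genes (43 measured, mean 0.04, adjusted p = 0.0393) lay near the threshold. With an estimated correlation the adjusted p was 0.815 for cell cycle and 0.496 for the matrix list, and they passed under 10 and 8 of 20 alternatives. Both calls were lost with no filter (0.0589 each), a mean TPM of at least 5 (0.079 each), eBayes without trend (0.068 and 0.0686), protein-coding genes only (0.0913 each) and without genes whose exons overlap another gene, a setting chosen after seeing the data (0.0645 and 0.131). Cell cycle genes also lost the call with quantile normalization (0.0532), and the matrix list with voom weights (0.0835) and the replicate number as a block (0.0542). Cell cycle genes turned direction without wild-type replicate 1 or K97E replicate 1 (means of -0.03 and -0.0094), and had means of 0.13 without wild-type replicate 2 and 0.11 without K97E replicate 2. The matrix list lost the call without wild-type replicate 1 (0.312) or K97E replicate 2 (0.449), with a mean of 0.02 in each case, and had a mean of 0.07 without K97E replicate 1. With other scalings, FPKM included, the means ran from 0.06 to 0.11 for cell cycle and from 0.07 to 0.10 for the matrix list. With voom weights they were 0.03 and 0.01. No member of these 5 lists passed over all genes or adjusted over the list alone.

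The remaining lists did not pass. Camera adjusted p was 0.518 for p53 targets, 0.965 for the unfolded protein and integrated stress response, 0.743 for heat shock, 0.946 for the immediate early and MAPK response and 0.358 for nuclear oxidative phosphorylation genes. It was 0.846 for cytosolic ribosomal proteins, 0.188 for calcium handling and ion channels and 0.740 for adipogenic and osteogenic markers. With a library left out, p53 targets passed without wild-type replicate 1 (0.0475), and calcium handling and ion channels without wild-type replicate 2 (0.0343) or K97E replicate 2 (0.0153). Ribosomal proteins passed with quantile normalization (0.0267). Among their members the death receptor Fas differed by -0.62, the growth factor Areg by -0.41, Etv4 by 0.40, Ndufa4 by 0.26 and lipoprotein lipase, Lpl, by -0.32. Other members went the opposite way, with Bax, a p53 target like Fas, at 0.19, the respiratory gene Cycs at -0.26 and the adipogenic gene Cebpa at 0.26. Without K97E replicate 1 Cycs stood at -0.15 and Cebpa at 0.43, and without K97E replicate 2 Cebpa stood at 0.08. With voom weights Etv4 stood at 0.25, Ndufa4 at 0.07 and Cebpa at 0.13. Markers of other cell types were too few at a mean TPM of 0.5 for a list test. Of leukocyte, endothelial, fibroblast and neural markers 4 each reached that level, and of 12 epithelial markers 0 did. Their examples Cd68, Flt1, Pdgfrb and Tubb3 differed by -0.31, -0.30, 0.19 and 0.12 on the log2 scale, with none past the test. The leukocyte marker Cd163 stood at 0.33, and the mean of the 4 leukocyte markers was -0.0036. With a library left out Cd68 ranged from -0.54 to -0.09, Tubb3 from -0.15 to 0.39 and Cd163 from -0.0090 to 0.67, each with its ends without wild-type replicate 1 and wild-type replicate 2.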

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

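The crossed pairing and the removal of genes with overlapping exons were chosen after seeing the data. The alternative without loci added by assembly was not run, since the files hold annotated transcripts only. Mfsd4a was called under 13 of 17 alternatives, with a log2 fold change from 2.66 to 4.37 and an adjusted p from 0.00219 to 0.912. Lmna kept its direction and was not called under any of 18. Against 1 gene higher and 0 lower, no filter gave 0 higher, TPM as deposited and eBayes without trend each 1 lower, voom weights 2 higher and 3 lower, and protein-coding genes only 3 lower, and the causes were not tested; all of these genes changed at least 2-fold. Same-numbered samples deviated with a correlation of -0.137 across genes and were not taken as pairs, though whether they share a day or batch is not known. With the replicate block 0 genes were higher and 0 lower, and of the called lists the extracellular matrix list was lost (0.0542). The crossed pairing as a block called 3 genes higher and 27 lower, of which 2 and 21 changed at least 2-fold. Besides Mfsd4a the named genes among them were Pdxp, higher, and Nos2, Lcn2, Frg2f1, Eif1ad14, Ifit1bl1, Cxcl1, Ccl11, Cxcl5 and Cxcl9, lower. Leaving out genes whose exons overlap another gene gave 0 higher, since Mfsd4a is among those removed. Leaving out each library in turn, with the lone sample of an arm assumed to vary like the others, gave 0 to 4 genes higher and 0 to 14 lower, all at least 2-fold. The highest counts came without wild-type replicate 1 (4 and 14), and without wild-type replicate 2 there were 2 and 4.

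Of 21 lists tested 11 were called, 7 lower and 4 higher. With an estimated correlation 0 were called and with fry 0. Both of these tests take their degrees of freedom from the few libraries and had little power, so their failure does not decide whether a list differs. Before adjustment p was 0.0361 for chemokines and 0.0600 for cholesterol genes by camera with an estimated correlation. By fry it was 0.0212 and 0.0315. With no filter 7 of 26 were called, and without overlapping genes 8 of 19. Leaving out a library gave 8 to 11, of 21 lists, or of 22 without either K97E library. Interleukins had an adjusted p of 0.0592 with no filter, 0.358 with an estimated correlation and 0.207 with fry, and chemokines 0.358 and 0.207 with the latter pair. Both passed under the other alternatives. Fry's adjusted p was 0.207 at the smallest of any list. The receptor list ranged from 0.00711 to 0.781 with a library left out, turning direction without K97E replicate 1 (0.741). Lists that were not called also turned the direction of the camera test, which is set against other genes, in some settings with no change in the sign of the list mean. The unfolded protein and integrated stress response had adjusted p of 0.924 with no filter, 0.737 with TPM as deposited, 0.801 with quantile normalization, 0.890 with FPKM as deposited, 0.927 with the crossed pairing and 0.838 without overlapping genes; of these the mean changed sign under TPM, quantile and FPKM. The immediate early and MAPK response had camera adjusted p of 0.978 with no filter, 0.938 without trend and 0.527 without overlapping genes. Of these settings its mean changed sign in the last alone. With TPM as deposited its mean was also positive, at 0.031, while the direction of the camera test held. The means kept their sign for adipogenic and osteogenic markers, at 0.978 with no filter, and ribosomal proteins, at 0.907 with protein-coding genes only. With a library left out, adjusted p ranged from 0.000153 to 0.952 for cell cycle, 0.164 to 0.334 for the unfolded protein response, 0.626 to 0.984 for heat shock, 7.2e-08 to 0.729 for mitochondrial transcripts and 0.455 to 0.870 for ribosomal proteins. It ranged from 0.0153 to 0.952 for calcium handling, 0.0475 to 0.887 for p53 targets (whose mean kept its sign at 0.887), 0.312 to 0.882 for the immediate early response and 0.0503 to 0.917 for oxidative phosphorylation. Of the named genes Cd163 ranged from -0.0090 to 0.67, Tubb3 from -0.15 to 0.39 and Nes from -0.070 to 0.15 on the log2 scale. The causes of these changes of direction were not tested. No setting with fewer reads was run, so what depth limits was not tested.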

Other observations

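The tests of Mfsd4a, Naca, leukocytes and the count of genes under other splits were chosen after the results were seen. The C2C12 libraries held abundant transcripts of the stem-cell antigen gene Ly6a (5039 to 5598 TPM) and osteopontin, Spp1 (5458 to 6025 TPM), in both groups; both genes were chosen after their values were seen. The 18S rRNA gene Rn18s took 2.35% and 4.44% of TPM in the wild-type libraries and 1.86% and 5.28% in the K97E libraries, so it did not follow the groups and was higher in replicate 2 of each.

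The Mfsd4a call may be set by how reads inside the Elk4 gene span were credited. In the K97E libraries at least 98.3% of the bases credited to Mfsd4a lay in 1 exon inside that span. The wild-type libraries had coverage in the 95 bp exon inside that interval, as this explanation requires. Moving the same reads between Mfsd4a transcripts would not be enough. Wild-type coverage of 49.9 and 60.1 over 95 bp falls far short of what was credited to the whole exon in the K97E libraries. Wild-type reads there would also have had to be left out or credited elsewhere. Elk4 itself stood at 35.1 TPM in both groups. Whether the rest of that exon held reads in the wild-type libraries cannot be seen in these values. In the K97E libraries it had a coverage of 112.5 and 103.6. The other exons of ENSMUST00000144548 lie outside the Elk4 gene span, where Mfsd4a exons reached at most 0.526 and 0 in these libraries. This argues against a rise of the spliced transcript. A rise of RNA from that interval alone stays open, as untested. Naca, named after its values were seen, had 543 and 363 TPM as group means. The coverage of exons shared by its transcripts had a ratio of 0.983, with 309 and 270 per gigabase against 279 and 290. The long transcript was credited 12.1 and 7.2 TPM with wild-type lamin A and 28.5 and 44.2 TPM with K97E. The exon that it alone has stood at 0.984 and 0.577 per gigabase against 0.557 and 0.615. The shared exons did not show the fall in TPM, which goes with reads being credited to another Naca transcript. The test was left undecided, because no bound on the ratio had been set.

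The lower inflammatory lists with K97E are a hypothesis for follow-up. Leukocytes in the cultures are argued against. Only 4 of 21 leukocyte markers reached a mean TPM of 0.5, and Tyrobp, C1qa, C1qb and C1qc were listed at 0 in all 4 libraries; Cd14, at 42.7 to 57.1 TPM, was the most abundant. Variation between libraries that follows no label cannot be told apart, because 4 libraries make 3 splits; another split called 1 of the 5 lists, interferon-stimulated genes, with an adjusted p of 1.87e-07. Of the chemokine mean 83.7% was kept after a trend of fold change on GC content and transcript length was removed. An effect of the mutant stays open, as untested. Each group received its own DNA and no untransfected cells were analysed here. Other differences between the transfections therefore cannot be told apart from an effect of the mutant.

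The higher cholesterol list may likewise be followed up. A trend of fold change on GC content and transcript length does not explain it, since 101% of the mean was kept after that trend was removed, with a value for 25 of 25 members. The other splits did not call the list, with a smallest camera adjusted p of 0.236. With only 3 splits, variation that follows no label cannot be excluded. It stays open beside an effect of the mutant, which was untested. Other differences between the transfections cannot be told apart from that effect here either.

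All 3 splits of the 4 libraries called at least as many genes as the real one, which called 1, with 2 as the highest of the others. For gene lists 1 of the 3 splits, the real one, called as many as 11, with 7 as the highest of the others. The splits are too few for a share under 0.05. The split of wild-type replicate 1 and K97E replicate 2 against the other pair gave 1574 genes at an unadjusted p under 0.05, against 600 for the real one.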
